A study of Mus musculus with 4 samples.

How the data were processed

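Expression was measured on 4 Affymetrix Mouse Gene ST arrays, 2 of control BR5FVB1-Akt cells and 2 of cells given 10 uM decitabine for 72 h. Per the labels' protocols, total RNA was extracted with a column kit, labelled with biotin by a whole-transcript kit and hybridised to the arrays. The deposited table holds 1 value per probe row and array, and its values were taken as log2 expression, because they have no missing cells and run from about 0.55 to 13.26, as log2 summaries of scanner intensities do. Neither the log base nor the summarisation, background correction or normalization is given in the sources used here. The array distributions were nearly but not exactly equal, and how the authors scaled them is not stated. If the values were logs of another base, the fold changes would differ. Scanner files were not used here, so no background or detection level could be set for any probe.

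Of 41345 rows, 23521 carried 1 gene symbol in the platform table, 1814 carried several and 16010 had none here. Of the rows with 1 symbol, 23328 had an Entrez identifier found in a RefSeq gene table of assembly GRCm38.p6, and 0 of their symbols needed an update. That table was used for names and chromosomes only, since the values come with no genome build, and no coordinates are given. Rows with several symbols or none were left out of the gene tests. For the 1082 genes with more than 1 row, the row with the highest mean over the 4 arrays was kept, which left 22180 genes. No filter on dim probes was applied in the comparison as designed. The table held 0 columns of other series.

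Groups and replicate numbers come from the sample titles. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. The prior had 3.07 degrees of freedom and an SD of 0.12. Fold changes are decitabine over control on the log2 scale with limma's standard error. Of the tested genes, 23.4% had both decitabine arrays above both control arrays and 22.5% had both below. Chance would give 33.3% for the 2 directions together. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

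The 22 gene lists, written before the data were examined, covered interferon-stimulated genes, nucleic acid sensing, MHC class I and class II antigen presentation, chemokines, cytokines and growth factors, NK and T cell ligands and checkpoint molecules, germline and cancer-testis genes, the Rhox cluster, imprinted genes, DNA methylation machinery, decitabine uptake and metabolism, p53 targets, mitosis, DNA replication, DNA repair, integrated stress and unfolded protein response, epithelial, mesenchymal and fibroblast, leukocyte and endothelial markers, and reference genes. Of 634 entries 565 were measured, and a gene may be in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 22 lists. Of these, 9 passed, all higher, and with an estimated correlation 0 passed. Members were also adjusted over the list alone. Chromosome shares were tested with Fisher's exact test over 21978 genes with a chromosome.

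The rule for named genes, also written beforehand, took up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with separated arrays, leaving out symbols of set forms, such as Gm plus digits or an ending in Rik. The RIKEN symbol 9930111J21Rik2 ends in Rik2, so the rule as written kept it. It added the 2 members of each list with the smallest p-value, whether or not they passed, and always Dnmt1, Dnmt3a, Dnmt3b, Actb and Gapdh. Genes named outside this rule are said in the text to be named after their values were seen.

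The alternatives were quantile normalization, centring of each array on its median, filters at the 25th percentile and the median of level, an intensity trend, robust eBayes, the replicate number as a block, the mean of a gene's rows, all rows, other thresholds, leaving out each array, camera with an estimated correlation, and fry. The fit was tested on simulated data for this comparison, 22180 genes in 20 sets with 200 changed genes each. It recovered 0.448% of genes changed 1.5-fold, 28.3% of those changed 2-fold and 91.6% of those changed 4-fold, and 4.44% of its calls were false. Lists of 30 genes shifted by 0.3 were called in 20 of 20 sets, and unshifted lists in 1 of 20. The simulated genes varied independently, with variances drawn without regard to level. These rates therefore need not hold for dim genes or for lists whose members vary together.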

Results

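Gene expression was measured in BR5FVB1-Akt cells, a mouse ovarian cancer line, cultured with or without decitabine. Decitabine is a cytidine analogue that is incorporated into replicating DNA and traps DNA methyltransferases there, which lowers DNA methylation. Total RNA from 2 control samples and from 2 samples given 10 uM decitabine for 72 h was hybridised to Affymetrix Mouse Gene ST arrays, 1 array per sample. The labels call the samples of a group biological replicates and do not say how they were cultured, so the p-values measured the spread between these 4 arrays. The deposited values were read as log2 expression from their range, and every fold change rests on that reading. The median over all 41345 rows was 4.60 on both control arrays and 4.60 and 4.66 on the decitabine arrays. Across the 22180 genes tested, which are not independent replicates, Pearson's r was 0.995 between the control arrays, 0.993 between the decitabine arrays and 0.990 to 0.991 between groups. The first principal component, with 50.4% of the variance, separated the groups, and the second, with 28.5%, parted the 2 decitabine arrays. With 2 arrays per group, the number of arrays limited the precision.

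The single comparison of the design asked which genes differed in expression after 72 h of decitabine. With decitabine 29 genes were higher and 3 lower, and 6 chemokine genes and 4 genes of the interferon-stimulated list were among those that rose. The largest rises were in 9930111J21Rik2, with a log2 fold change of 2.65 ± 0.11 (SE, 2 arrays per group), and in Ankrd1, an ankyrin repeat protein of the nucleus and the sarcomere, with 2.41 ± 0.14, a 5.33-fold difference. The next were the interferon-induced genes Usp18, which removes ISG15 from proteins (2.19 ± 0.19), and Rtp4 (2.12 ± 0.17), followed by the chemokine Ccl5 (2.07 ± 0.10). Apol9b, an apolipoprotein L family gene, rose by 2.05 ± 0.17, the polo-like kinase Plk2 by 1.99 ± 0.11, and Ifit1, whose product binds foreign RNA, by 1.98 ± 0.10. The calls of Usp18, Rtp4 and Apol9b were lost with quantile normalization (adjusted p = 0.0588, 0.0506 and 0.0506) and with robust eBayes (adjusted p = 0.0591, 0.0519 and 0.0527), while the log2 fold change of Usp18 was 2.18 and 2.19. The 3 genes that fell were Tmem178 (−1.93 ± 0.14), the angiopoietin-like gene Angptl7 (−1.66 ± 0.11) and the calpain family gene Capn6 (−1.37 ± 0.10).

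In levels, Ankrd1 went from 7.34 ± 0.20 (SD, n = 2) on the control arrays to 9.75 ± 0.09 on the decitabine arrays, and Ifit1 from 5.30 ± 0.07 to 7.27 ± 0.02. Tmem178 went from 9.12 ± 0.04 to 7.19 ± 0.22. The control level of 9930111J21Rik2, 2.08 ± 0.03, lay near the bottom of the range of the arrays, and its decitabine level was 4.73 ± 0.11. Both 9930111J21Rik2 and Apol9b have closely similar gene copies, so which copy their probes measured is uncertain. In the order of the preceding paragraph, the array row identifiers of these genes were 17262241, 17364176, 17462437, 17324446, 17266946, 17312686, 17289794 and 17358832 for those that rose, and 17339967, 17432976 and 17545106 for those that fell.

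Among the remaining genes that rose, named after their values were seen, were the prostaglandin synthase Ptgs2 (1.95 ± 0.14), the iron-siderophore binding protein Lcn2 (1.77 ± 0.12), the protease inhibitor Serpinb2 (1.67 ± 0.13), the scaffold protein Tgfb1i1 (1.57 ± 0.13), the ephrin receptor Epha4 (1.49 ± 0.10), the transcription factor Myc (1.48 ± 0.12) and the phosphatase Dusp4 (1.23 ± 0.10). In limma with Benjamini-Hochberg adjustment, the adjusted p of the 32 genes lay between 0.0261 and 0.0495. Each of them differed by at least 2-fold, and its decitabine arrays lay both above or both below its control arrays. With so few arrays the threshold itself nearly requires both properties, so they add no support. At an unadjusted p under 0.05 there were 1629 higher and 1545 lower genes. With an intensity trend in the variance model, 817 genes were higher and 798 lower, the 32 among them. When all 41345 rows were fitted with such a trend, 165 rows of tested genes passed. The calls with the trend thus depended on which rows were fitted. Robust eBayes kept 18 of the 32, while the replicate number as a block (smallest adjusted p = 0.106) and a test of all rows (smallest adjusted p = 0.282) kept 0. No gene passed when any of the 4 arrays was left out, while the log2 fold changes then ranged from 2.57 to 2.73 for 9930111J21Rik2, from 2.27 to 2.56 for Ankrd1, from 1.93 to 2.03 for Ifit1 and from −2.09 to −1.78 for Tmem178.

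**Figure D1:**
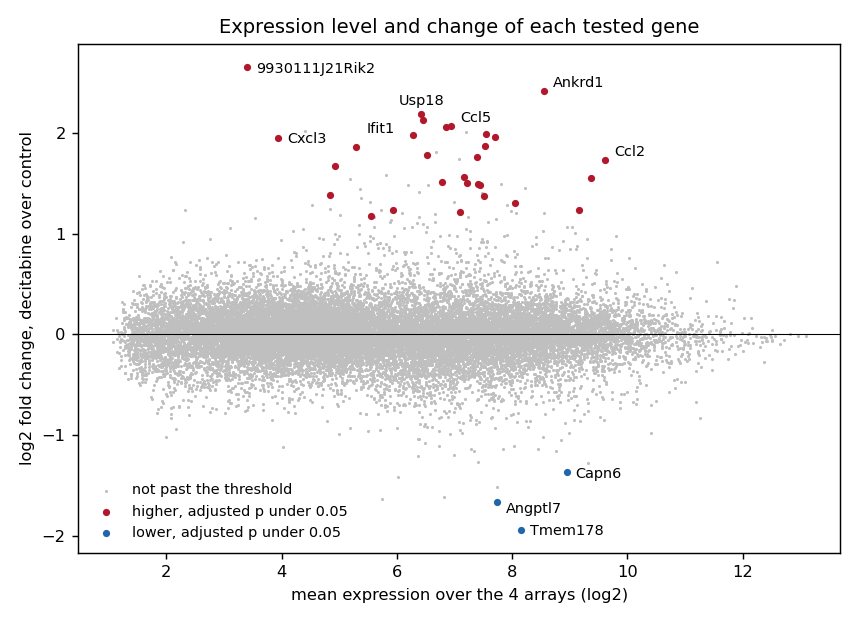
Log2 fold change of decitabine over control against mean log2 expression over the 4 arrays, 1 point per tested gene. The 29 genes past the threshold and higher are red, the 3 lower ones blue, and a few of them are named. Cxcl3 and 9930111J21Rik2 lie at the dim end of the arrays.

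Interferon-stimulated genes shifted upward as a group. Of 41 measured members, 4 rose over all genes tested (Ifit1, Usp18, Rtp4 and Gbp3), and 32 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 0.90, and 37 of the 41 were positive. Gbp3, a guanylate-binding protein, rose by 1.38 ± 0.11. Of the 4, Usp18 and Rtp4 did not pass with quantile normalization, and these 2 and Gbp3 (adjusted p = 0.0510) did not pass with robust eBayes, so Ifit1 alone passed in both. Among members named after their values were seen, the transcription factor Irf7 (1.74 ± 0.16), the oligoadenylate synthetase-like gene Oasl2 (2.01 ± 0.19) and the ubiquitin-like modifier Isg15 (1.41 ± 0.16) rose over the list alone, Ifi204 fell (−0.60 ± 0.11), and Ifit3 was at −0.04 ± 0.14. Against all other genes the list was higher in camera with its preset correlation (adjusted p = 6.78e-24), and the call was lost with an estimated correlation (adjusted p = 0.459). In fry, which tests the list by itself, the adjusted p was 0.0325.

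The genes of nucleic acid sensing, most of whose products detect RNA or DNA in the cytosol or endosomes, were also higher as a list, though not throughout. Their median was 0.28 over 18 members, with 14 positive and 4 negative. Without a trend none passed over all genes tested in limma, with 8 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, 8 rose. These included the RNA sensor gene Ddx58, at 1.17 ± 0.14, a 2.24-fold difference, and the Z-nucleic acid sensor gene Zbp1, at 1.00 ± 0.11. Ifih1, another RNA sensor gene, was at 0.69 ± 0.12, and the RNA-editing enzyme gene Adar at 0.86 ± 0.12, both named after their values were seen. The count of 8 became 2 without control replicate 1, 5 without decitabine replicate 1 and 4 without decitabine replicate 2. The list was called higher in camera (adjusted p = 6.90e-05), and not with an estimated correlation (adjusted p = 0.459). In limma with the intensity trend 8 members were higher and 1 lower over all genes. The lower one was Mavs (adjusted p = 0.0352). Sting1 (0.891), Irf3 (0.697), Tbk1 (0.280) and Ticam1 (0.902), named like Mavs after their values were seen, did not pass in that fit. Whether this list shifted separately from the interferon-stimulated genes was not tested. Leukocyte markers, measured on the same arrays, had a median of 0.08.

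Of 30 measured chemokine genes, 6 rose over all genes tested and 10 rose adjusted over the list alone, while the list's median was 0.14. The 6 were Ccl5, the neutrophil attractants Cxcl3 (1.95 ± 0.10) and Cxcl1 (1.22 ± 0.10), the monocyte attractants Ccl2 (1.73 ± 0.14) and Ccl7 (1.51 ± 0.10), and the T cell attractant Cxcl10 (1.76 ± 0.11). All but Ccl5 and Cxcl3 were named after their values were seen. The control level of Cxcl3, 2.96 ± 0.05 (SD), lay at the dim end of the arrays. No background level was set there, so the size of its rise is uncertain. Cxcl10 went from 6.51 ± 0.14 (SD, n = 2) to 8.27 ± 0.05. The T cell attractants that share a receptor with Cxcl10, likewise named afterwards, did not pass, with Cxcl9 at 0.11 ± 0.25 and Cxcl11 at 0.09 ± 0.12. In camera the list was higher (adjusted p = 1.04e-05), which was not so with an estimated correlation (adjusted p = 0.481). Among 29 cytokine and growth factor genes, 2 rose over the list alone, Il1a (1.05 ± 0.16) and Lif (0.64 ± 0.12). The list as a whole had a median of 0.01 and an adjusted p of 0.666 in camera.

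**Figure D2:**
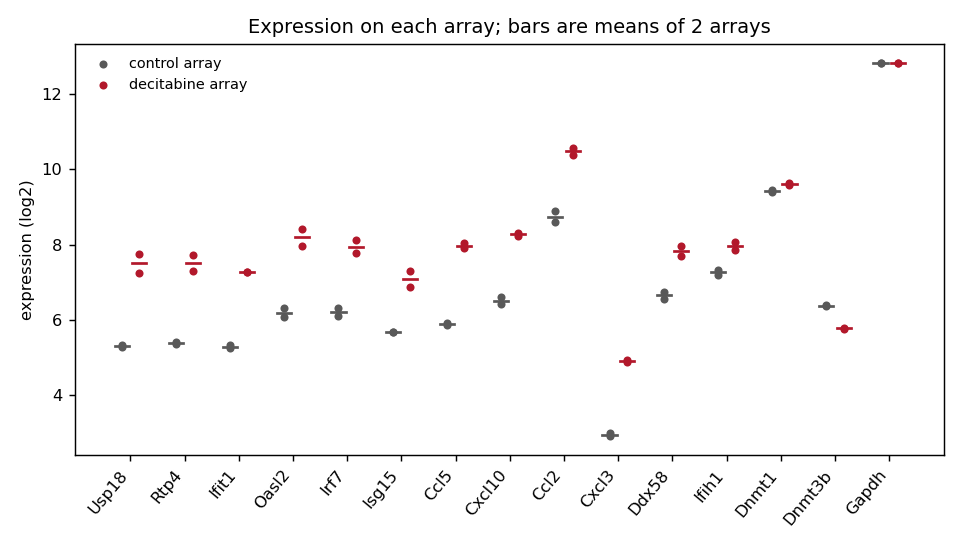
Log2 expression of 15 genes on each of the 4 arrays, with control arrays in grey, decitabine arrays in red and a bar at the mean of each group. For the interferon-stimulated, chemokine and sensor genes shown, some chosen after their values were seen, both decitabine arrays lie above both control arrays, while Dnmt3b is lower and Gapdh, at 0.00 log2, differs by less than its replicate spread and changes sign with centred arrays.

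Genes of antigen presentation showed smaller differences. Of 20 genes of the MHC class I pathway, none passed over all genes or over the list alone in limma without a trend. At an unadjusted p under 0.05, 5 were higher and 0 lower. The immunoproteasome subunit genes Psmb8 (0.53 ± 0.10) and Psmb10 (0.45 ± 0.10) had the pathway's smallest p-values. With the intensity trend 3 of the 20 were higher over all genes, Psmb8 and Psmb10 among them, and 1 was lower. The list's median was 0.06, with an adjusted p of 0.0898 in camera and 0.0327 in fry. For the 10 MHC class II genes the median was 0.02, the mean −0.05 and the direction in camera downward (adjusted p = 0.916), and H2-DMb1 (0.32 ± 0.13) and H2-DMb2 (−0.38 ± 0.17) lay on either side of 0. Among 26 ligands of NK and T cells and checkpoint molecules, the adhesion molecule Vcam1 (1.06 ± 0.10) and the poliovirus receptor Pvr (0.78 ± 0.11) rose over the list alone, and Clec2d, named after its value was seen, fell. That list had a median of −0.03 but a mean of 0.11, and camera put it upward (adjusted p = 0.299).

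Gene classes known to be silenced by DNA methylation in somatic cells showed no called change in the reported fit. None of the 59 germline and cancer-testis genes passed over all genes or over the list alone in limma, with 5 higher and 1 lower at an unadjusted p under 0.05. The RNA helicase gene Ddx4 was at 0.57 ± 0.15 and Taf7l, a germ cell transcription factor subunit, at 0.37 ± 0.10. When only genes above the median level were tested in limma, Ddx4 passed as higher (adjusted p = 0.0390). The median of the list was 0.04 (camera, adjusted p = 0.503). For 58 of the 59 members the 95% confidence interval excluded a 2-fold rise, and 53 of the 59 lay below the median level of all genes. The intervals come from the fit without a trend and may be too narrow for dim genes. Of 9 genes of the Rhox homeobox cluster on the X chromosome, none passed in limma, and 1 was higher at an unadjusted p under 0.05. Rhox5 was at 0.66 ± 0.21 and Rhox1 at −0.18 ± 0.10. The Rhox median was −0.03 and the mean 0.05 (camera, downward, adjusted p = 0.991), a direction that turned upward with centred arrays.

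Of 32 imprinted genes, none passed in limma, with 2 higher and 4 lower at an unadjusted p under 0.05 and a median of −0.10 (camera, adjusted p = 0.187). The paternally expressed gene Peg3 was at −0.33 ± 0.10 and the maternally expressed gene Phlda2 at 0.43 ± 0.10. With the intensity trend 5 imprinted genes, Igf2, Peg3, Mest, Dlk1 and Grb10, were lower and 0 higher, all but Peg3 named after their values were seen. The de novo methyltransferase gene Dnmt3b was the 1 member of 16 genes of the DNA methylation machinery to fall over that list alone, from 6.38 ± 0.02 (SD, n = 2) to 5.77 ± 0.03 (log2 fold change −0.60 ± 0.10). Dnmt1, which maintains methylation, was at 0.19 ± 0.10, Dnmt3a at −0.18 ± 0.12 and the glycosylase gene Mbd4 at −0.33 ± 0.09. At an unadjusted p under 0.05, 2 members were higher and 2 lower. With the intensity trend, Uhrf1 (0.28 ± 0.11) and Hells (0.31 ± 0.11), named after their values were seen, were higher and Dnmt3b lower. The list's median was −0.04 and its adjusted p 0.503 in camera and 0.0139 in fry, downward. Among 21 genes of decitabine uptake and metabolism, the nucleoside diphosphate kinase gene Nme1 (0.49 ± 0.10) and the efflux transporter gene Abcg2 (0.62 ± 0.13) rose over the list alone. This list was higher in camera with a median of 0.09 (adjusted p = 0.00639, and adjusted p = 0.481 with an estimated correlation), which was lost without decitabine replicate 1 (adjusted p = 0.0551).

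**Figure D3:**
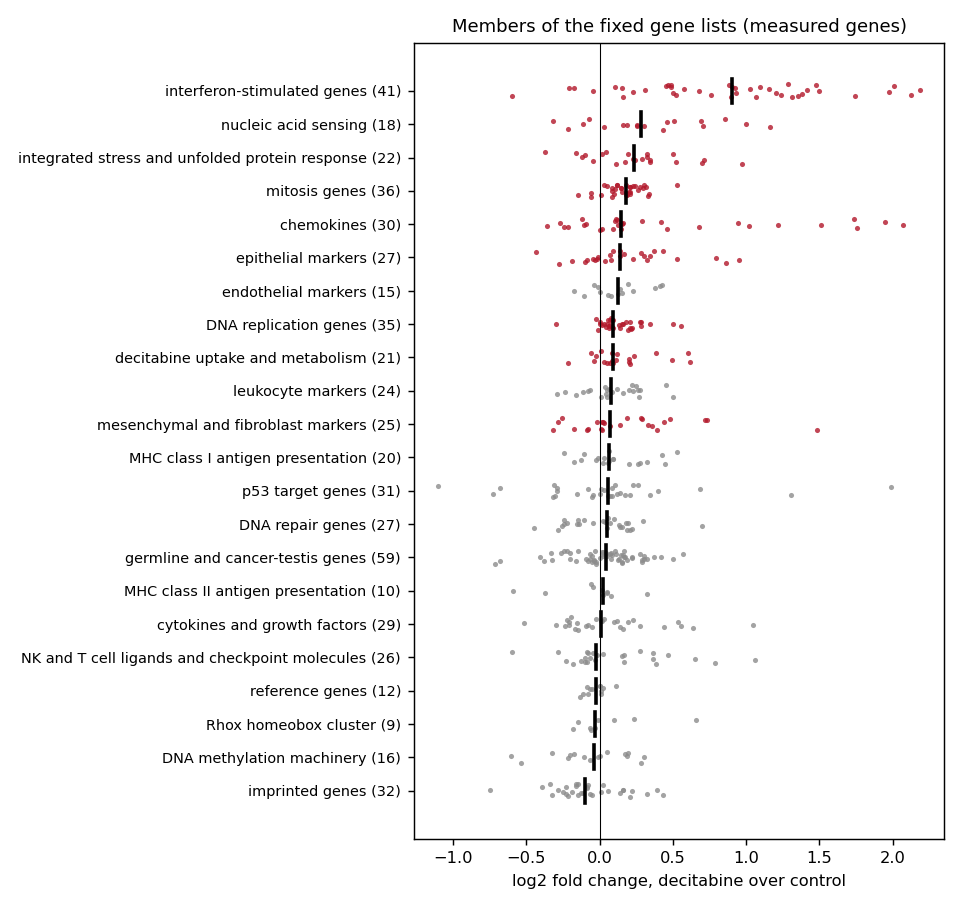
Log2 fold change of decitabine over control for each measured member of the 22 gene lists, 1 point per gene, with a bar at each list's median and the number of measured members in brackets. Red lists had an adjusted p under 0.05 in camera with its preset correlation. The interferon-stimulated genes have a median of 0.90, and the other lists lie between −0.10 and 0.28.

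Targets of p53 moved in both directions. Plk2 rose over all genes tested, and of 31 members 3 rose and 3 fell over the list alone. The cell cycle inhibitor gene Cdkn1a, at 1.31 ± 0.12, was 2.48-fold higher. Those that fell, named after their values were seen, were the mTOR inhibitor gene Ddit4 (−1.11 ± 0.13), Sesn1 (−0.73 ± 0.15) and Trp53inp1 (−0.68 ± 0.12). The list's median was 0.06 (camera, adjusted p = 0.636). The integrated stress and unfolded protein response genes were higher in camera, with a median of 0.23 over 22 members (adjusted p = 3.61e-04, and adjusted p = 0.481 with an estimated correlation). Over that list alone 5 rose and 1 fell (Sdf2l1, named after its value was seen), and those that rose included the transcription factor genes Ddit3 (0.71 ± 0.10) and Nupr1 (0.70 ± 0.12). The count of 5 became 0 to 2 when any 1 array was left out.

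Mitosis genes had a median of 0.18 over 36 members and DNA replication genes one of 0.09 over 35, both higher in camera (adjusted p = 6.90e-05 and 8.39e-04) and neither with an estimated correlation (adjusted p = 0.632 and 0.481). Without an intensity trend no member of either list passed in limma over all genes or over the list alone. At an unadjusted p under 0.05, 6 mitosis genes were higher and 0 lower, as were 4 and 1 replication genes. The scaffold gene Anln (0.53 ± 0.12) and the kinesin gene Kif20b (0.34 ± 0.10) led the former, and the origin licensing genes Cdc6 (0.55 ± 0.10) and Mcm10 (0.50 ± 0.10) the latter. With the intensity trend 6 mitosis genes were higher and 0 lower over all genes, and 5 replication genes were higher and 1 lower. The mitosis list differed by 0.19 between the 2 control arrays, and its call was lost without control replicate 1 (adjusted p = 0.141). None of 27 DNA repair genes passed in limma without the trend, with 1 higher and 2 lower at an unadjusted p under 0.05. Fancb was at 0.70 ± 0.17 and the alkyl-DNA repair gene Mgmt at −0.45 ± 0.14, and the median of the list was 0.05 (camera, adjusted p = 0.916). In limma with the intensity trend Fancb passed as higher (adjusted p = 0.0303) and Mgmt as lower (adjusted p = 0.0459).

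Markers of cell types that the culture could hold were compared in the same way. Epithelial markers had a median of 0.14 over 27 members (camera, adjusted p = 0.00639, and adjusted p = 0.481 with an estimated correlation), and the surface protein gene Msln (0.86 ± 0.10) and the keratin gene Krt14 (0.79 ± 0.10) rose over that list alone. Mesenchymal and fibroblast markers had a median of 0.07 over 25 members (adjusted p = 0.0280, and adjusted p = 0.481 with an estimated correlation), and Thy1 (1.48 ± 0.17), the smooth muscle actin gene Acta2 (0.72 ± 0.10) and Fn1, named after its value was seen, rose over the list alone. The epithelial call was lost without decitabine replicate 1 (adjusted p = 0.0514), and the mesenchymal call without it (adjusted p = 0.162) or without control replicate 2 (adjusted p = 0.0592). Among genes above the 25th percentile of level or above the median level, the mesenchymal list did not pass either (adjusted p = 0.0780 and 0.0544). At an unadjusted p under 0.05 in limma, 8 epithelial markers were higher and 1 lower, as were 6 and 1 mesenchymal markers. With the intensity trend 6 epithelial markers were higher and 2 lower over all genes, and 6 mesenchymal markers higher and 1 lower. The lower ones, named after their values were seen, were Wt1 and Upk3b, and Pdgfra.

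None of 24 leukocyte markers passed in limma, with 2 higher and 0 lower at an unadjusted p under 0.05. Cd68 was at 0.45 ± 0.10, and passed with the intensity trend (adjusted p = 0.0216), and Itgam was at 0.50 ± 0.11. The list's adjusted p was 0.0895 in camera, and the list was called higher without control replicate 1 (adjusted p = 0.0314) or without decitabine replicate 1 (adjusted p = 0.0226). None of 15 endothelial markers passed either, with 3 higher and 0 lower unadjusted. Their median was 0.12 (camera, adjusted p = 0.0898, and adjusted p = 0.0190 without control replicate 1), with Cdh5 at 0.43 ± 0.14 and Kdr at 0.38 ± 0.12. The 12 reference genes had a median of −0.03 (camera, adjusted p = 0.574), and none passed at an adjusted or an unadjusted p under 0.05 in limma. Among them Actb was at 0.11 ± 0.11, Rplp0 at −0.13 ± 0.12 and Tfrc at −0.11 ± 0.11. Gapdh was at 0.00 ± 0.09, a sign that turned negative with centred arrays (−0.02) and with the mean of a gene's rows (−0.04).

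No gathering of the 29 higher or the 3 lower genes on any of 21 chromosomes was detected, though sets this small could miss one. In Fisher's exact test, two-sided and adjusted over chromosomes, 0 chromosomes passed for either set, and 0 did so at an unadjusted p under 0.05. For the higher genes the smallest unadjusted p in that test were 0.0622 for chromosome 11, 0.0644 for 16 and 0.0761 for 1. Chromosome 11 held 5 of the higher genes, among them Ccl2, Ccl5 and Ccl7, and the X chromosome 0. The 3 higher genes of chromosome 5 were Cxcl1, Cxcl3 and Cxcl10. With 4 arrays split into 2 and 2, an exact permutation test of a single gene gives no two-sided p below 0.333, so every gene call depended on the variance that limma shares across genes.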

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

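The tests of technical explanations in this part were all chosen after the results they bear on had been seen. Some rows outside the tested genes, those with several gene symbols, with none, or beyond a gene's brightest row, also differed between the groups. In a fit of all rows with an intensity trend, 21 of these 19165 rows passed, 12 higher and 9 lower with decitabine, beside 165 rows of tested genes, and without the trend 0 of the 19165 did. Of the 21, 19 had several symbols or none here and were not named, and 2 of the 21 held identical values. The other two were second rows of Prss23 (1.56 ± 0.14), whose brightest row is among the 29 higher genes, and of Nid1 (0.88 ± 0.10).

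The interferon-stimulated genes had medians of 0.85 and 0.95 on the decitabine arrays relative to the control mean, and a median log2 fold change of 0.90. Leukocytes in the treated cultures, as the whole cause, are argued against by the leukocyte markers, with a median of 0.0755: the 95% confidence interval of each of the 24 lay below 0.90, although probes near background may understate a rise. These intervals come from the fit without a trend and may be too narrow for dim markers. A smaller share stays open, since Cd68 was at 0.45 ± 0.10 and passed with the intensity trend (adjusted p = 0.0216), and the leukocyte list was called higher without control replicate 1 (adjusted p = 0.0314) or decitabine replicate 1 (0.0226), within a range of 0.0226 to 0.620 over the arrays left out. The list's median was 0.900 after quantile normalization and 0.877 with centred arrays. The array medians, 4.60 on both control arrays and 4.60 and 4.66 on the decitabine arrays, were already close. Differences in scale left in the deposited values were thus too small to give the shift. The authors' own scaling is not stated and could not be tested this way. An effect of decitabine stays a hypothesis from the same 4 arrays. Whether interferon genes were transcribed at harvest could not be told: 18 interferon genes had a median of −0.0392, and Ifnab was lower, but 12 of them had a signal below the median of all genes, where a rise from almost no transcript may be compressed.

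The germline and cancer-testis genes, a class that decitabine often raises, had no called member in the reported fit. Ddx4 passed only when the test was limited to genes above the median level. That dim probes on these arrays cannot give a call is argued against by 2 genes, 9930111J21Rik2 and Cxcl3. They were called higher from control levels of 2.08 and 2.96, below the list's median control level of 3.81. In all, 5567 genes lay below that level. The log2 fold changes of the 2 were 2.65 and 1.95, so they do not show that a smaller rise could be called there. Lower precision of dim probes stays open as part of the explanation, since the median SD between arrays of a group was 2.00 times as large for genes below the median level (0.167) as for those above it (0.0835). Even so, the 95% confidence interval excluded a 2-fold rise for 58 of 59 members on the scale of these values, which may understate changes near background. The intervals come from the fit without a trend, while the list's median same-group SD was 0.170. They may therefore be too narrow for the dim members. A lack of response in these cells remains open as the biological alternative.

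The upward shift of the mitosis list, with a median of 0.18, is matched by a difference between arrays of 1 group. The same genes differed by 0.187 between the 2 control arrays and by 0.036 between the 2 decitabine arrays. A difference in growth between cultures of the same group could therefore give a shift of this size, and an effect of decitabine on these genes was not separable from it here. Control replicate 2 minus 1 was 0.059 for DNA replication genes (list median 0.090) and −0.050 for mesenchymal markers (list median 0.071). Their shifts are thus not clearly separable from such differences either. For the other called lists the difference between control arrays was smaller relative to the shift. It was −0.040 for decitabine uptake and metabolism (list median 0.089). Between the decitabine arrays, chemokines differed by 0.093 (list median 0.14). The median shifts of these lists are thus not clearly separable from same-group differences either.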

How the results depend on the processing

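All alternatives were chosen before the data were examined. The 2 arrays per group, the unknown normalization and the lack of a background level limit every result. The deviations of same-numbered arrays correlated at −0.018 across genes, so no strong effect shared by a replicate number was seen. Whether same-numbered samples were prepared together is not stated, and this value cannot settle it. With the replicate number as a block, limma called 0 genes, 0 higher and 0 lower, with 1423 higher and 1392 lower at an unadjusted p under 0.05. That fit has 1 residual degree of freedom fewer, and it kept the 9 list calls. Without any 1 array the counts ranged from 0 to 0 in each direction, with 1007 to 1640 genes higher and 846 to 1635 lower unadjusted. The lone array of a group is then assumed to vary like the others. Testing all rows called 0 genes, with 1901 higher and 1923 lower unadjusted. Robust eBayes called 18 (15 higher), all among the 32. The pseudocount alternative was not run, because the values are logs.

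Other settings called more genes. Centring gave 51 genes (43 higher, 8 lower), the filter at the 25th percentile 215 (151 higher, 64 lower), the filter at the median 1251 (635 higher, 616 lower), the intensity trend 1615 (817 higher, 798 lower), the mean of a gene's rows 36 (31 higher, 5 lower), and an adjusted p under 0.10 154 (114 higher, 40 lower). Of the 32 genes these kept 32, 31, 28, 32, 32 and 32. Dim genes were noisier, so a shared variance without a trend makes fewer calls among bright genes, and the near balance of directions in the larger sets differs from the 29 to 3 of the reported fit. Quantile normalization called 29 of the 32 and no other gene.

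Of the 9 list calls, quantile normalization, centring, the block and the trend kept 9, while leaving out 1 array gave 7 to 10. With an estimated correlation 0 passed: adjusted p was 0.459 for interferon-stimulated genes and for nucleic acid sensing, 0.632 for mitosis, and 0.481 for chemokines, decitabine uptake, DNA replication, the stress response, epithelial and mesenchymal markers. Nucleic acid sensing and mesenchymal markers lost their calls although their estimated correlations, −0.0553 and 0.00884, lay below the preset 0.01. The other called lists had estimates above it, the highest being 0.735 for mitosis. It was 0.167 for DNA replication, 0.141 for chemokines and 0.130 for interferon-stimulated genes, so the preset may be too low for such lists. The estimates rest on few residual degrees of freedom, so these losses neither show nor exclude that correlation among members gave the calls. In fry 4 lists passed. Adjusted p was 0.0327 for MHC class I and 0.0139 for DNA methylation machinery, newly past the threshold. It was 0.0529 for chemokines, decitabine uptake and the stress response, 0.299 for mitosis, 0.150 for DNA replication and mesenchymal markers, and 0.0899 for epithelial markers, all no longer past it. Mesenchymal markers also lost the call at the 25th percentile filter (0.0780) and at the median filter (0.0544), where NK and T cell ligands passed (0.0456).

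Directions turned only in results that had passed no threshold. The Rhox list turned upward with centring (0.979), the 25th percentile filter (0.914), the trend (0.828) and the block (0.836), and MHC class II upward with that filter (0.807) and in fry (0.988). Gapdh turned negative with centring (−0.0204) and with the mean of a gene's rows (−0.0392). On leaving out 1 array, directions turned for Gapdh and Rhox without control replicate 1, for germline genes without control replicate 2 (0.835), and for Rhox, MHC class II, p53 targets (0.935) and DNA repair (0.695) without decitabine replicate 1.

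Leaving out 1 array gave these ranges of adjusted p: Rhox 0.586 to 0.835, MHC class II 0.591 to 0.808, germline genes 0.141 to 0.946, p53 targets 0.481 to 0.935, DNA repair 0.620 to 0.965, mitosis 3.17e-09 to 0.141, leukocyte markers 0.0226 to 0.620, endothelial markers 0.0190 to 0.470, mesenchymal markers 0.0138 to 0.162, decitabine uptake 0.00878 to 0.0551, and epithelial markers 0.00307 to 0.0514. Gapdh ranged from −0.00535 to 0.0142. Members higher over the list alone ranged from 2 to 8 for nucleic acid sensing, from 0 to 2 for the stress response, from 24 to 31 for interferon-stimulated genes and from 8 to 10 for chemokines. The stress response count was 8 at the 25th percentile filter, 11 at the median filter and 11 with the trend. Beyond what fewer arrays, fewer genes or a trend imply by construction, the cause of these changes was not tested.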

Other observations

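The directions of the 3 gene groups below were noticed among the most changed genes, and the lists were written then, so they are hypotheses. Their tests left out the members seen among the most changed genes when the lists were written. Of the members tested, Tagln is also on the mesenchymal and fibroblast list, whose results were already tabulated. Genes of cholesterol and fatty acid synthesis were lower with decitabine as a group. Over 22 such members the median log2 fold change was −0.403 and 21 were negative. Without a trend none passed over all genes tested in limma, with 0 higher and 16 lower at an unadjusted p under 0.05. Over the list alone 14 were lower. With the intensity trend 0 were higher and 16 lower over all genes. Examples are Pmvk (−0.69 ± 0.13), which acts in the mevalonate pathway, the fatty acid desaturase gene Scd1 (−0.70 ± 0.13), the squalene synthase gene Fdft1 (−0.62 ± 0.11) and the sterol demethylase gene Cyp51 (−0.61 ± 0.14). Among members seen before, Insig1 was at −0.84 ± 0.10. Of 10000 random lists matched on level, the central 95% had medians between −0.095 and 0.095. Those lists held unrelated genes, so they do not show how far genes of a pathway vary together between cultures. The members tested share a pathway with those seen before, so this was not an independent test. In camera over the 3 lists the adjusted p was 1.57e-11, and it was 0.127 with an estimated correlation. The list differed by 0.12 between the control arrays and by −0.12 between the decitabine arrays. A lower sterol regulatory programme is a candidate explanation, not tested further here.

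Genes known as targets of YAP and SRF, regulators of the actin cytoskeleton and of growth, were higher as a group. The median over 30 tested members was 0.329, or 0.321 over the 29 without Tagln. In camera the adjusted p was 5.54e-12, and it was 0.0699 with an estimated correlation. With the intensity trend 18 of the 30 were higher and 0 lower over all genes in limma. Without it none passed, with 17 higher and 0 lower unadjusted, and 14 were higher over the list alone. They included the calponin gene Cnn1 (0.98 ± 0.17), Fhl2 (0.72 ± 0.13), Ccn1 (0.62 ± 0.14) and the tropomyosin gene Tpm1 (0.43 ± 0.10). Ankrd1 and Ccn2 (1.41 ± 0.17) were among those seen before. NF-kB targets other than chemokines had a smaller shift, with a median of 0.213 over 19 tested members, 15 of them positive (camera, adjusted p = 1.34e-04, and adjusted p = 0.0802 with an estimated correlation). Without the trend none of these passed over all genes in limma, with 9 higher and 0 lower unadjusted. Over the list alone 1 was higher, Ier3 (0.61 ± 0.11). With the intensity trend 5 of the 19 were higher and 0 lower over all genes. Mesenchymal and fibroblast markers, a list that shares Acta2 and Tagln with the YAP and SRF list, were also higher in camera (adjusted p = 0.0280). That call was lost with an estimated correlation (adjusted p = 0.481), without decitabine replicate 1 (adjusted p = 0.162) and without control replicate 2 (adjusted p = 0.0592), among other settings. Changes in cell shape or density after 72 h of treatment could raise such genes too, and the arrays do not tell these apart.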
